A study of Drosophila melanogaster with 4 samples.

How the data were processed

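Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map Su(var)3-7 in nuclei of third-instar larvae of the wild-type *Drosophila melanogaster* strain Oregon-R. The antibody is called Q3448 in the labels. The study held 4 libraries, 2 of immunoprecipitated chromatin and 2 of input chromatin. Each input library served as the control of the immunoprecipitated library of the same number, per the labels. Nothing in the labels says that the replicates came from separate populations of larvae. The SDs over the 2 replicates may therefore reflect technical spread only. The p-values below describe clusters and their positions within these libraries and measure no spread between replicates.

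Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The deposited files were 3 lists of regions on FlyBase release 5 of the genome, per the file headers. There was 1 list for each ChIP replicate and 1 list for the replicate set. The program that called the clusters, its significance threshold, its width minimum and the way in which the replicates were combined are not given in the sources used here. The deposited value of each cluster was read as a log2 enrichment of ChIP over input made by the authors. The log2 scale was inferred from the values, because repeated values lay exactly 1 apart. The value of a cluster is the authors' own and was used to describe, rank or filter clusters. It was also used to test differences between medians within a list and to correlate overlapping clusters of the replicates. The lists held no read counts and no value for the input libraries, so the depth is unknown and no interval that needs a read count is given.

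Sequence lengths were taken from the file headers, which named 14 sequences. Clusters were listed on 13 of them, and the unplaced sequence Uextra (29.0 Mb) had none in any list and was left out. In each list 1 cluster ran past the end of its sequence and was clipped to it. The 13 sequences were grouped as 4 large autosome arms (2L, 2R, 3L and 3R), the X arm, chromosome 4, 6 scaffolds assigned to heterochromatin (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet) and the unplaced sequence U. The covered share of a sequence was the percent of its bases under at least 1 cluster. Assembly gaps and positions at which reads could not be placed uniquely were not removed from the lengths.

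Overlap of the replicates was measured as the bases under clusters of both lists divided by the bases under clusters of either (the Jaccard index), and as the share of clusters overlapped by at least 1 bp. It was tested with a one-sided permutation test of 10000 circular shifts of the replicate 2 list within each sequence, in which the smallest possible p was 0.0001. Shifts of 20 to 200 kb were added after the data had been seen. Cover near the ends of arms was the ratio of the covered share in a window to that of the rest of the arm, averaged over the replicates. The window was the centromere-proximal 2 Mb of the 5 large arms, or the distal 100 kb of those arms and of chromosome 4. It was tested with a one-sided permutation test of 10000 circular shifts in which both lists moved together, with Benjamini-Hochberg adjustment over the arms. Differences between medians of clusters were tested with two-sided permutation tests of 100000 resamples, in which the smallest possible p was 1e-05. Clusters within a list are not independent samples, so these p-values describe the list.

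The regions named in the text followed a rule fixed before the data were examined. It took the 10 clusters of the replicate-set list with the highest value that overlapped a cluster of both replicates, with at most 3 per sequence, then the 5 widest clusters and the highest of each chromosome class. The highest of a class, as named in the text, is the highest among clusters found in both replicates. The designs of the tests and most of the alternatives were fixed at the same point. The alternatives were the higher-scoring portion of each list, equal list lengths, merging of clusters closer than 1 kb, a width minimum of 1 kb, other window sizes, stricter overlap rules, other sequence lengths, counts of clusters in place of bases, the replicate-set list and each replicate alone. Use of the bases under clusters of both replicates, the distal ratio without chromosome 4 and other thresholds for the length of proximal domains were added after the data had been seen.

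The tests were tested on simulated data. For overlap and proximal tests, simulated clusters were narrower than 10 kb and lay at random on the 5 large arms, apart from planted effects. Those for the proximal test numbered 437 per list. The deposited clusters were wider in part and concentrated near proximal ends, so error rates for such lists were not tested. Independent lists gave p under 0.05 in 0 of 20 pairs, and lists that shared 10% of their clusters in 20 of 20. A planted proximal ratio of 5 was recovered as 4.86 and passed in 20 of 20 draws, against 1 of 20 with nothing planted. A planted difference of 0.1 log2 between medians passed in 19 of 20 draws, against 1 of 20 with none. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

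The gene table at hand belonged to release 6 of the genome and the cluster lists to release 5, so no cluster was assigned to a gene. The planned counts of genes under clusters and the tests of 8 gene lists holding 179 genes were therefore not run.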

Results

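Su(var)3-7 is a zinc-finger protein of *Drosophila* heterochromatin and a partner of HP1, known from mutations that weaken the silencing of genes placed beside heterochromatin. Its binding in nuclei of third-instar Oregon-R larvae was recorded in 2 ChIP libraries, each called against 1 of 2 input libraries. Replicate 1 held 5994 enriched clusters over 19.9 Mb, and replicate 2 held 5617 clusters over 18.9 Mb, or 14.3% and 13.5% of the 13 sequences with clusters. The list of the replicate set held 11471 enriched clusters over 33.9 Mb (24.3%) and 5 depleted regions. Clusters had a median width of 2090 bp in replicate 1, 2075 bp in replicate 2 and 1846 bp in the replicate-set list. Their median enrichment over input was 0.70, 0.73 and 0.46 on the log2 scale. The read depth behind these values is unknown, because the lists hold no counts. All coordinates are on FlyBase release 5.

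The distribution over chromosomes was compared to ask where a heterochromatin protein lay along the genome. The 6 heterochromatin scaffolds were the most densely covered class, with 51.1% ± 3.22 (SD, n = 2) of their bases under clusters. Chromosome 4, a small and largely heterochromatic autosome, followed with 38.6% ± 0.27 (SD, n = 2). The 4 large autosome arms had 10.98% ± 1.03 (SD, n = 2), the X arm 8.34% ± 0.43 (SD, n = 2) and the unplaced sequence U 16.7% ± 0.82 (SD, n = 2). Relative to the large autosome arms, cover was 4.69-fold ± 0.73 (SD, n = 2) on the heterochromatin scaffolds and 3.52-fold ± 0.31 (SD, n = 2) on chromosome 4, and each replicate alone exceeded 3-fold for both.

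Among the scaffolds, 3LHet was the most covered, at 61.2% in replicate 1 and 66.1% in replicate 2, ahead of 2RHet at 51.9% and 58.0%. 2LHet (42.0% and 51.0%), 3RHet (40.5% and 43.4%) and XHet (38.0% and 33.4%) lay between these and the arms. YHet stood apart, with 2.93% and 3.25% of its bases under 5 and 7 clusters, less than any large arm. These few clusters had median log2 values of 1.57 in replicate 1 and 1.55 in replicate 2, above those of the scaffolds as a class. In the replicate-set list 12.1% of YHet was covered. The scaffold is 0.35 Mb long, and positions at which reads could not be placed uniquely were not removed. Low cover there need not mean little binding. Among the large arms 2R was the most covered (17.1% and 15.2%) and 3R the least (7.79% and 6.30%). Clusters on the heterochromatin scaffolds were also more enriched than those on the large autosome arms, by 1.46-fold in replicate 1 and 1.54-fold in replicate 2 at the median. Enrichment did not follow cover in every class: the medians were 1.05-fold and 1.04-fold on the densely covered chromosome 4, and 1.59-fold and 1.62-fold on U. An exact permutation test over 2 paired replicates cannot give a two-sided p under 0.5, so no test across samples was made. The fold for the heterochromatin scaffolds was 8.07 in the higher-scoring portion of each list, 3.10 in the replicate-set list and 2.75 by number of clusters per Mb.

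**Figure D1:**
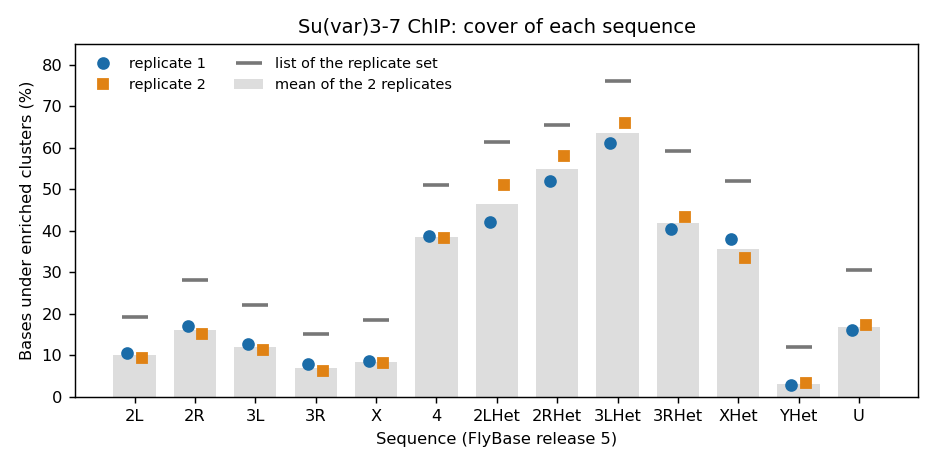
Percent of the bases of each sequence under enriched clusters. Points show replicates 1 and 2, bars their mean and dashes the replicate-set list. The heterochromatin scaffolds other than YHet, and chromosome 4, lie at 33.4% or more in both replicates, and all 5 large arms at 17.1% or less.

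The most enriched regions lay largely in unplaced and heterochromatic sequence. The cluster with the highest value in the replicate-set list that was found in both replicates lay on U at 9552098 to 9555061, with a log2 enrichment of 3.74 (3.54 in replicate 1 and 3.78 in replicate 2). The highest value of that list as a whole was 3.96. The highest cluster of each class is likewise given among those found in both replicates. On the heterochromatin scaffolds it was 3RHet 1712250 to 1715951, at 3.21 (3.11 and 3.72). 3L 24451743 to 24464751, next to the proximal end of that arm, was the highest of the large autosome arms at 2.58. On chromosome 4 the highest cluster was 4 6390 to 24817, at 2.18 over 18.4 kb. The X arm held a narrow site at X 18132418 to 18134620, with 2.85 (2.71 and 3.01) over 2.20 kb. The replicates were further apart at others of the 10 highest: U 10035139 to 10037675 had 2.66 in replicate 1 and 5.59 in replicate 2. Clusters of replicate 1 covered only 28.9% of 2RHet 2431595 to 2437803 and 27.2% of 3L 24087434 to 24092422, against 85.01% and 83.36% for replicate 2. Of the 100 highest values in the replicate-set list, 79 lay on the grid of repeated values described below. Few reads are a candidate explanation for these. The replicate-set values of the 10 highest regions found in both replicates did not lie on that grid, so it does not bear on their order. The number of reads behind them is unknown, and their replicate differences may partly rest on few reads.

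The 5 widest clusters of the replicate-set list lay at the proximal ends of chromosome 2. The widest was 2RHet 368135 to 476817, which spanned 108.7 kb at a log2 enrichment of 1.92 and was 97.9% and 98.2% covered by clusters of the replicates. It was followed by 2L 22579018 to 22658757 (79.7 kb, 1.32) and 2R 1434366 to 1510474 (76.1 kb, 1.40). The remaining 2 of the 5 widest were 2R 374595 to 434352 (59.8 kb, 1.55) and 2R 958012 to 1015633 (57.6 kb, 1.59). Clusters of 10 kb or more made up 9.58% and 13.5% of those on the heterochromatin scaffolds in replicates 1 and 2, and 10.5% and 13.4% of those in the proximal 2 Mb of the large arms. They made up 1.37% and 0.81% in the rest of the arms, 2.61% and 2.55% on chromosome 4, and 1.71% and 2.02% on U. The width threshold of 10 kb was chosen after the data had been seen, and these shares were not tested. The 5 widest regions were divided into up to 7 clusters in a replicate, and the widest single cluster of replicate 1 lay on 3L (50773 bp, against 50142 bp on 2R).

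Within the assembled arms, cover was compared between the centromere-proximal 2 Mb and the rest. The proximal windows of the 5 arms were 43.8% covered in replicate 1 and 43.0% in replicate 2, against 8.14% and 6.80% elsewhere. On 2R the window from 1 to 2000000 was 69.7% and 71.2% covered, on 3L that from 22543558 to 24543557 was 56.5% and 59.4% covered, and on 2L that from 21011545 to 23011544 was 47.2% and 46.6% covered. On 3R the window from 1 to 2000000 reached 31.5% and 23.7%. On X the window from 20422828 to 22422827 reached 14.21% and 13.97%, against 8.10% and 7.46% in the rest of the arm.

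The proximal ratio over all 5 arms was 5.85 ± 0.66 (SD, n = 2; one-sided circular-shift permutation test, p = 0.0001, the smallest the shifts can give). It was 7.27 ± 0.83 on 2L and 6.84 ± 1.14 on 2R (SD, n = 2; permutation test, adjusted p = 0.005 for both), 7.46 ± 1.44 on 3L (permutation test, adjusted p = 0.014) and 5.03 ± 0.36 on 3R (permutation test, adjusted p = 0.011). The ratio of 1.82 ± 0.08 on X did not pass (SD, n = 2; permutation test, adjusted p = 0.17), and the difference between X and the other arms was not tested. With a 1 Mb window X passed at 2.81 (permutation test, adjusted p = 0.027), and by number of clusters per Mb 2R no longer passed at 2.23 (permutation test, adjusted p = 0.090). The ratio over all arms was 11.6 in the higher-scoring portion of each list, 3.26 in the replicate-set list and 2.72 by number of clusters per Mb.

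The length of the proximal domains, measured from the end of each assembled arm, differed between arms. Whether the assembled arms end at like distances from the centromere was not tested. Consecutive 250 kb windows covered to at least 50% reached 1.75 Mb and 1.5 Mb from the proximal end on both 2R and 3L in replicates 1 and 2. They reached 1.25 Mb and 1 Mb on 2L and 0.25 Mb in both replicates on 3R. On X the first window was 22.1% and 19.1% covered, below that threshold. The lengths depended on the threshold of 50%, and lower ones were added after the data had been seen. At 20% they were 4.25 Mb and 3.75 Mb on 2R, 2.5 Mb and 1.75 Mb on 3L, 1.5 Mb in both replicates on 2L, 1.5 Mb and 0.25 Mb on 3R, and 0.25 Mb and 0 Mb on X. At 10% they reached 6 Mb and 6.25 Mb on 2R, 5 Mb and 2.5 Mb on 3L, 2.25 Mb and 1.5 Mb on 2L, 1.5 Mb in both replicates on 3R, and 0.25 Mb and 1.25 Mb on X.

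**Figure D2:**
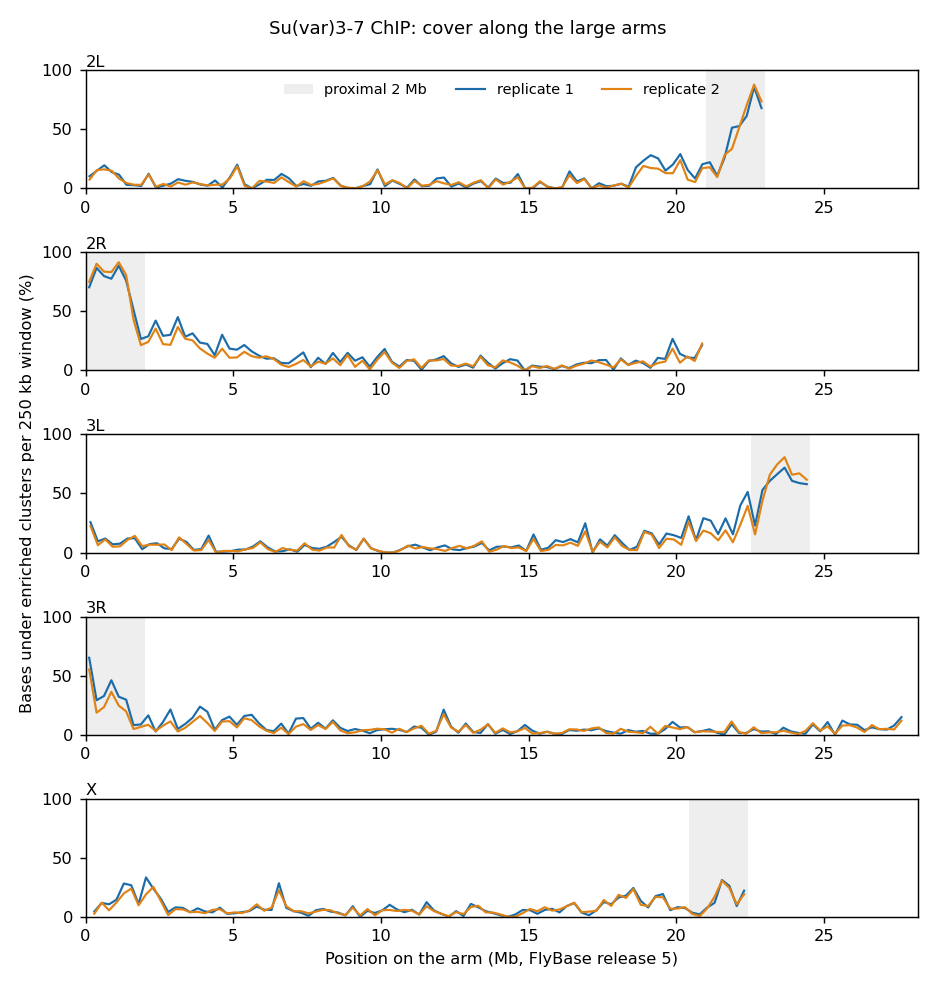
Percent of bases under enriched clusters in 250 kb windows (vertical axis) against position in Mb along the 5 large arms, for replicates 1 and 2. Grey marks the centromere-proximal 2 Mb, where cover rises above 50% on 2L, 2R, 3L and 3R and stays below 50% on X.

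The distal ends were compared in the same way, since heterochromatin proteins are also known at telomeres. On chromosome 4 the distal 100 kb, from 1251858 to 1351857, was 58.7% and 54.6% covered in replicates 1 and 2, against 37.2% and 37.1% in the rest. The distal 100 kb of 3L was 17.3% and 20.7% covered and that of X 13.02% and 11.99%. Those of 2L (1.43% and 0%), 2R (0% and 2.06%) and 3R (4.10% and 2.74%) were less covered than the rest of their arms. The ratio over all 6 was 1.45 ± 0.10 (SD, n = 2; one-sided circular-shift permutation test, p = 0.39). Chromosome 4 is densely covered and supplies as large a window as each arm, although it is only 1.35 Mb long. That alone raises the ratio over all 6 without any distal enrichment, and the circular shifts carry the same imbalance. None of the 6 passed alone (permutation test, adjusted p from 0.44 to 0.88). Without chromosome 4, an alternative added after the data had been seen, the ratio was 0.70 ± 0.08 (SD, n = 2, permutation test, p = 0.59). The windows of the 5 large arms were 7.17% and 7.49% covered, against 11.15% and 9.85% elsewhere. Elsewhere takes in the proximal 2 Mb, which were 43.8% and 43.0% covered and lower the ratio. Outside the proximal 2 Mb the arms were 8.14% and 6.80% covered. The distal windows lay below that in replicate 1 and above it in replicate 2, so the ratio below 1 does not show a distal deficit.

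Because the dose of Su(var)3-7 is known to change the X polytene chromosome of males, X was compared with the autosomes outside the proximal 2 Mb. X was 8.10% and 7.46% covered there in replicates 1 and 2, and the 4 large autosome arms 8.15% and 6.65%. The ratio was 1.06 ± 0.09 (SD, n = 2), and X ranked 3 and 2 among the 5 arms. Clusters on the whole X arm had a median enrichment 0.09 higher on the log2 scale than those on the large autosome arms in both replicates. Among 5 arms the smallest exact p that a rank allows is 0.2, so no test was made. The ratio lay below 1 in replicate 1 (0.99) and above it in replicate 2 (1.12). It was 1.72 in the higher-scoring portion of each list and 0.76 over whole arms.

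The clusters of the replicates were compared by position. The bases under clusters of both made up 60.97% of those under either. Overlap was highest on 3LHet (84.9%) and 2RHet (82.1%), intermediate on 2R (61.1%) and lower on X (46.2%), 3R (45.0%) and YHet (28.6%). Among these sequences the order followed cover, but not throughout the 13 sequences. Chromosome 4 had more overlap than 2LHet (77.2% against 69.55%) at less cover (38.6% against 46.5%). The mean overlap by circular shifts was 46.6% on 3LHet and 37.8% on 2RHet, but 8.99% on 2R, 4.36% on X, 3.63% on 3R and 1.74% on YHet. The ratio of observed overlap to that mean was lowest on 3LHet and 2RHet among these. A high mean by shifts leaves this ratio little room, so it does not rank the agreement of the replicates. Of the clusters of replicate 1, 4160 (69.4%) overlapped a cluster of replicate 2, and 4170 of those of replicate 2 (74.2%) overlapped a cluster of replicate 1. For the clusters of replicate 1 the mean share was 28.96% by circular shifts and 36.2% by shifts of 20 to 200 kb. Replicate 1 had more cover than replicate 2 on all 4 large autosome arms, X and chromosome 4, but on only 1 of the 6 heterochromatin scaffolds, XHet.

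Circular shifts gave a mean overlap of 13.03% and a highest of 19.8% (one-sided permutation test, p = 0.0001, the smallest the shifts can give). Shifts of 20 to 200 kb, which keep the distribution along a chromosome and were added after the data had been seen, gave a mean of 20.8% and a highest of 22.6% (permutation test, p = 0.0001). Over the large arms the overlap was 54.0% against a mean of 6.07% by shifts, and over chromosome 4 and the heterochromatin scaffolds 79.5% against 35.8%. By shifts of 20 to 200 kb these means were 15.9% and 37.3%. For the 3135 pairs of clusters that overlapped one to one, Pearson's r between the log2 values of the replicates was 0.87 and Spearman's rho 0.80. For the 2150 pairs on the large arms r was 0.77 and rho 0.64. These are across clusters, which are not independent replicates.

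**Figure D3:**
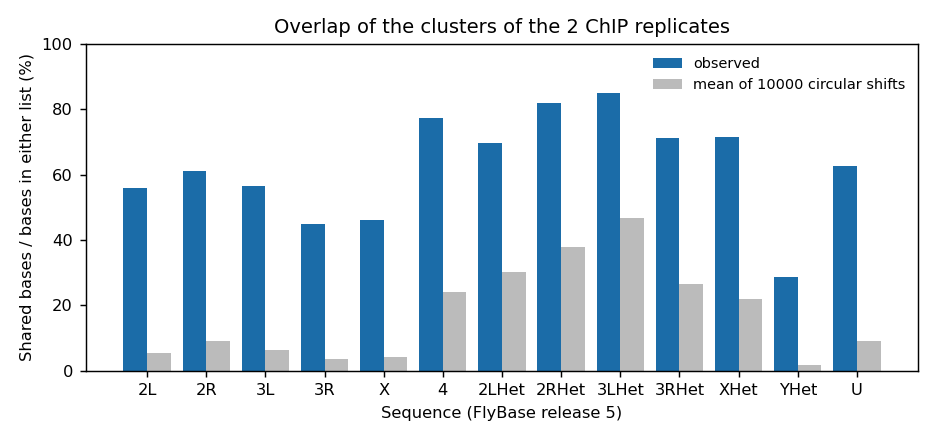
Bases under clusters of both replicates as percent of those under either, by sequence, with the mean of 10000 circular shifts. Observed overlap runs from 28.6% on YHet to 84.9% on 3LHet and lies above the mean of the shifts on all 13 sequences.

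Clusters found in both replicates had higher log2 values and larger widths than those found in 1. In replicate 1 the median log2 enrichment was 0.82 for the 4160 shared clusters and 0.59 for the 1834 others, and the median width 2713 bp against 1584 bp. In replicate 2 the medians were 0.80 for 4170 shared clusters and 0.62 for 1447 others, and 2435 bp against 1593 bp. The differences in log2 enrichment, 0.22 and 0.18, and those in width passed a two-sided permutation test over clusters (p = 1e-05 for each, the smallest the resamples can give). On the large arms alone the differences in log2 enrichment were smaller, at 0.12 and 0.11, and passed the same permutation test (p = 1e-05 for each). A wider cluster meets the 1 bp overlap rule more often by position alone, so the difference in width is partly built into the rule, and the log2 values were not compared at equal width.

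The replicate-set list was then set against the replicates. Its clusters overlapped 99.2% of the clusters of replicate 1 and 99.0% of those of replicate 2. Of its own clusters, 3519 (30.7%) overlapped clusters of both replicates, 2898 (25.3%) those of 1 replicate and 5054 (44.1%) those of neither. The clusters found in both held 60.9% of the bases of the list, had a median width of 4036 bp and a median log2 enrichment of 0.71. Those found in neither had a median width of 1264 bp and a median of 0.43. By class, 64.0% of clusters on the heterochromatin scaffolds and 57.7% of those on chromosome 4 were found in both replicates, against 27.0% on the large autosome arms and 23.8% on X. The list was made from the same libraries, so these shares are not independent evidence and were not tested.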

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

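The tests in this part were chosen only after the results had been seen. The list of the replicate set held 5 regions marked as depleted, a class that neither replicate list contained and that no comparison above used. Their log2 values lay between -0.12 and -0.02. 3 of them overlapped clusters called as enriched in replicate 2, and 1 overlapped a cluster of replicate 1. The region at 2R 16965026 to 16966956 lay wholly under an enriched cluster of replicate 2, and 2R 7021124 to 7022816 overlapped no cluster of either replicate.

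The replicate-set list also held 5054 clusters found in neither replicate. The narrowest cluster was 1001 bp wide in that list and 1301 bp wide in both replicate lists. A smaller width minimum is argued against as the whole account, since 53.9% of these clusters (95% exact binomial interval 52.5 to 55.3%) were narrower than the replicate minimum and 2331 were not. Weak enrichment may account for part of them, since on the large arms their median log2 enrichment differed by -0.18 from that of clusters found in both replicates (two-sided permutation test, p = 1e-05, the smallest the resamples can give). That stays open, because the median of clusters found in neither (0.42) was not below that of the 2487 clusters found in 1 replicate (0.41; two-sided permutation test, p = 0.11). No biological explanation was tested.

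Cover of the proximal 2 Mb of X was 0.28 of that of the 4 large autosome arms in both replicates. A lower read depth on X, as a mixture of sexes could give, is argued against as the sole source of this gap. Outside the proximal 2 Mb the ratio of X to autosome cover was 0.99 in replicate 1 and 1.12 in replicate 2, against 0.28 within it in each. A smaller effect of depth stays open, since the read depth is unknown. Whether the assembled X arm ends farther from the centromeric heterochromatin than the other arms was not tested. That remains an open explanation, which concerns the assembly.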

How the results depend on the processing

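All alternatives named here were chosen before the data were examined, except use of the bases under clusters of both replicates, the shifts of 20 to 200 kb and the distal ratio without chromosome 4. No paired analysis was possible because the cluster lists hold no value for the input libraries, so ChIP and input of the same number could not be set against each other. Ratios between classes were taken within each replicate. Of 45 main values with a test, 44 kept their direction and side of the threshold, whatever their size, and 1 turned. Of 24 without a test, 13 moved by less than the spread between replicates (or the binomial interval) and 11 by more. A further 6 came from 1 replicate alone and cannot exceed that spread, so they show no stability. The overlap of the replicates ranged from 54.0% to 79.5%, and the proximal ratio over all arms from 2.72 to 11.6 (highest permutation p = 0.0002). The distal ratio ranged from 0.70 to 2.03 and passed under no alternative. It was 0.70 without chromosome 4, which was the value that turned. The ratio with chromosome 4 is raised by the dense cover of that chromosome, so this does not show a distal enrichment that reversed. The ratio without chromosome 4 is lowered by the densely covered proximal ends, so it does not show a distal deficit.

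The cover of the heterochromatin scaffolds relative to the large autosome arms was 8.07 in the higher-scoring portion of each list, 3.10 in the replicate-set list, 2.75 by number of clusters per Mb and 5.78 over the bases of both replicates. That of chromosome 4 was 4.21, 2.47, 3.21 and 4.29 under the same settings. The ratio of X to the autosomes was 1.72 in the higher-scoring portion and 0.76 over whole arms, and 0.99 in replicate 1 alone, so its side of 1 was not kept. The value over whole arms takes in the proximal ends. The share of the replicate-set list found in both replicates was 21.5% with reciprocal overlap, a rule that can only lower it. The higher-scoring portion keeps more of a class with higher values. Median log2 values were 1.17 and 1.26 on the scaffolds, 0.71 and 0.72 on X and 0.69 in both replicates on chromosome 4. On the large autosome arms they were 0.62 and 0.64. In the proximal 2 Mb they were 0.87 and 0.86, against 0.62 and 0.63 in the rest of the large arms. The rises in that portion, also of the proximal ratio, are thus partly built into the filter. For the other changes the cause was not tested.

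Of 121 proximal and distal ratios of single arms and chromosome 4 under alternatives, 115 kept their direction and call, 1 passed only under an alternative (the proximal ratio of X with a 1 Mb window) and 1 no longer passed (that of 2R by number of clusters per Mb). The distal ratio of 3L fell below 1 in the replicate-set list (0.97), by number of clusters per Mb (0.78) and with a 50 kb window (0), and that of X with a 200 kb window (0.90), none of which had passed. The width minimum of 1 kb removed no cluster, so it tests nothing. The alternatives for genes under clusters and gene lists were not run for lack of an annotation of the same release, and leaving out a replicate gives no value for the overlap. The unknown depth leaves open how far the number of clusters in each list was set by sequencing.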

Other observations

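The tests and regions in this part were chosen only after the results had been seen. Outside the proximal 2 Mb, several stretches of the large arms were covered above the median window of their arm in both replicates. Among 250 kb windows more than 3.5 Mb from the proximal end, 2R 3500001 to 3750000 was 31.4% covered in replicate 1 and 25.5% in replicate 2, and 3L 20293558 to 20543557 30.7% and 26.1%. On X the windows 1922828 to 2172827 (33.4% and 19.0%) and 6422828 to 6672827 (28.4% and 22.4%) were covered more than the median window of that arm (5.94% and 5.88%). The window at 6422828 lay above both neighbours in each replicate, whereas that at 1922828 was part of a wider stretch, with 23.7% and 25.3% in the next window. The 2R window likewise lay beside one with 28.5% and 26.8%, in a run of windows covered to at least 10% that extended from the proximal end for 6 Mb and 6.25 Mb. The 3L window at 20293558 lay within such a run of 5 Mb in replicate 1 but not in replicate 2 (2.5 Mb). The distal window 3L 43558 to 293557 was 25.7% and 22.5% covered. The widest cluster in the X window at 6422828 was 13913 bp in replicate 1 and 12954 bp in replicate 2.

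Many clusters of the highest log2 values took repeated values. In the replicate-set list, 79 of the 100 highest lay at a fixed offset plus the log2 of a whole number or a whole number and 0.5, within a relative tolerance of 1e-05, against 2.36% of the other clusters. The offset was chosen on the other clusters alone. The counts were 17 of 100 in replicate 1 and 24 of 100 in replicate 2, and 3 rules for the offset were tried in turn, of which the others gave 79 and 83 in the replicate-set list, 33 and 7 in replicate 1 and 24 and 31 in replicate 2. A candidate explanation is that few reads stand behind these values, and identical copies of a repeat remain open beside it, since 38 of 78 clusters with a repeated value (48.7%, 95% exact binomial interval 37.2 to 60.3%) matched a partner in width within 5 bp. Of the 100 highest, 13 lay on the large arms, against 81.2% of the others, and no biological explanation was tested.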
